A study of Mus musculus with 4 samples.

How the data were processed

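RNA of polymorphonuclear myeloid-derived suppressor cells (PMN-MDSC, neutrophil-like cells that restrain T cell responses) purified from the spleens of newborn C57BL/6 mice was sequenced in 4 libraries. Per the labels' protocols, the purified cells had been treated for 5 days with NECA, a stable adenosine analogue that activates adenosine receptors, or with the solvent DMSO, and 300000 cells of each condition were lysed. Complementary DNA was made with the SMARTer chemistry, amplified by PCR, cut with a fragmentase and sequenced as read pairs on a NovaSeq instrument, per the labels' protocols. Each group held 2 libraries, numbered 1 and 2 in the labels. The labels do not say whether the 2 libraries of a group came from separate animals or separate treatments. The p-values therefore measure only the spread between these samples, which need not be that between animals or treatments.

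The deposited tables give, per the file headers, a whole-number read count and an FPKM value (fragments scaled by gene length and library size) for each of 54532 Ensembl genes in each library. HISAT, StringTie and edgeR, with no versions, and the builds mm10 and GRCm38 are named in the submitters' processing notes. The counting program, the annotation release, the treatment of reads that match several genes and the use of strand are not given in the sources used here. In the deposited FPKM values the ratio of count to FPKM differed between libraries by 1 factor for all 9004 genes with at least 50 counts in every library, with a largest relative departure of 4.6e-09. The FPKM columns were therefore the same counts divided by a length per gene and a scale per library. Relative to DMSO replicate 1 those scales were 0.985, 0.947 and 0.804 for DMSO replicate 2, NECA replicate 1 and NECA replicate 2, and the totals of the counts were 0.995, 1.01 and 0.854.

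The counts were analysed as deposited, in R 4.3.3. Of the gene symbols, 27 that had been turned into calendar dates were restored from their Ensembl identifiers, 54409 identifiers matched the reference gene names, and 54495 had a position in GENCODE M21 on GRCm38, from which all coordinates below are taken. Where a listed symbol belonged to more than one identifier, the identifier with the higher mean count was used. Genes were kept by filterByExpr of edgeR 4.0.16 with its default settings (minimum count 10), libraries were scaled by TMM, and NECA was tested against DMSO with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest). The p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The model had 2 residual degrees of freedom and no replicate block. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are given as CPM on the TMM-scaled library sizes.

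Before the data were examined, the comparison, the tests, 30 lists of genes (pathways, stress responses, granule classes and markers of neutrophils and of other cell types), the alternatives and the rule for named genes were fixed. The lists overlap and hold 724 symbols, of which 5 matched no gene in the tables. Each list with at least 5 tested members (29 lists) was tested against the other genes with camera of limma 3.58.1, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The named genes were the 12 with the largest fold change in each direction among genes at adjusted p under 0.05 with a mean of at least 20 CPM, both NECA libraries on the same side of both DMSO libraries and a symbol that is not a provisional one. Up to 4 members of each list with the smallest p-values and 19 genes of adenosine and suppressor cell biology were added whatever their values. Other genes named in the text were chosen after their values were seen. Some genes that the rule takes are not reported here.

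Depth was 15864120 to 18712625 counts per library. Data were simulated from the means, the spread per gene and the library sizes of these 4 libraries (13083 genes), with each gene drawn independently. In them 200 genes with a mean of at least 5 CPM were changed, and the members of a simulated list were raised 1.5-fold besides. Of the 200, the test recovered 70.1% of genes changed 1.5-fold, 94% of genes changed 2-fold and 100% of genes changed 3-fold. Of its 197 calls 12 were genes simulated without a change. These rates do not apply to genes below 5 CPM. Nor do they cover genes that shift together between libraries, as the B cell markers did (camera's estimated correlation of 0.96). The 2 libraries of a group were not copies of the same counts (chi-square per degree of freedom of 6.75 for DMSO and 5.27 for NECA). Xist had 204 and 64.1 CPM in DMSO replicates 1 and 2, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in replicate 1. The median of the B cell markers, as log2 CPM relative to the DMSO mean, was -0.93 and -3.85 in NECA replicates 1 and 2. These values argue against technical repeats of the same RNA in either group. They do not show that the animals or the treatments were separate. Counting noise is that of amplified fragments without molecular identifiers. Alternatives were DESeq2 size factors and upper-quartile scaling, no filter and a stricter filter on low counts, the DESeq2 1.42.0 test, limma-voom, a replicate block, leaving out each library in turn (the lone library of a group was then assumed to vary like the other group), and limma on log2(FPKM + 1) or log2(FPKM + 0.1) of genes with a mean FPKM of at least 1. Library size alone as the scale, thinning of every library to the smallest total and removal of the genes of other cell type lists were added after seeing the data. Near-identical gene copies were sought by BLAST among the GENCODE transcripts (at least 95% identity over at least 200 bases), and counts of genes with such copies, overlapping genes or antisense partners are described as uncertain.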

Results

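The expression of 54532 genes was counted in spleen PMN-MDSC of newborn mice after 5 days with NECA or with DMSO, 2 libraries in each group. Total counts were 18583918 and 18492030 in DMSO replicates 1 and 2 and 18712625 and 15864120 in NECA replicates 1 and 2. In the same order, 18756, 18422, 18842 and 18220 genes had at least 1 count. The most abundant transcripts were those of neutrophils: Ngp (2.93% of all counts), Ltf (2.87%), S100a9 (2.68%), S100a8 (1.64%) and Lyz2 (1.38%), which encode granule and cytosolic proteins. The 10 most abundant genes held 14.9% and 15.4% of the counts with DMSO and 15.7% and 15.9% with NECA. Transcripts of haemoglobin held 0.113% and 0.0449% of counts with DMSO and 0.0299% and 0.00148% with NECA. Those of the mitochondrial genome held 0.350% and 0.385% with DMSO and 0.305% and 0.309% with NECA. Across genes, log2 CPM of replicates correlated at r = 0.986 for DMSO and r = 0.983 for NECA (genes are not independent replicates). Between groups, NECA replicate 1 correlated with DMSO replicates 1 and 2 at r = 0.984 and 0.983, and NECA replicate 2 at r = 0.972 and 0.971. By this measure NECA replicate 1 was about as close to the DMSO libraries as to NECA replicate 2.

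The comparison of NECA with DMSO asks what activation of adenosine receptors changes in these cells, in a series whose title links adenosine, suppressor cells and necrotizing enterocolitis of the newborn. Of 28 tested markers of monocytes and macrophages, 14 were lower with NECA, 0 were higher and 14 did not pass edgeR's test. Among the lower ones were Vcam1, a cell adhesion molecule, C1qa, C1qb and C1qc, the subunits of complement C1q, and Hmox1, the haem-degrading enzyme. Vcam1 fell from 83.1 ± 1.44 to 25.0 ± 4.65 CPM (SD, n = 2 each) and C1qc from 38.6 ± 2.09 to 10.9 ± 2.11 CPM. Fewer genes rose, and most of them by less: Gapdh, a glycolytic enzyme, rose from 43.6 ± 1.55 to 154 ± 14.0 CPM, and Cpt1a, which passes fatty acids to mitochondria for oxidation, from 130 ± 11.7 to 192 ± 13.3 CPM. Counts of Gapdh are uncertain because it has 90 annotated near-identical copies. Summed with them, its log2 fold change was 1.10, against 1.82 alone. Of 13083 genes tested with edgeR's quasi-likelihood test, 46 were higher and 128 lower at adjusted p under 0.05, with a median fold change of 1.30 among the higher genes and a median fall of 2.79-fold among the lower ones. Only 1 higher gene but 93 lower genes had changed at least 2-fold. The higher genes were abundant (median of 156 CPM) and the lower ones were not (median of 7.56 CPM). Of the 129 tested genes on the lists of other cell types, 0 were higher and 19 were lower by edgeR's test.

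**Figure D1:**
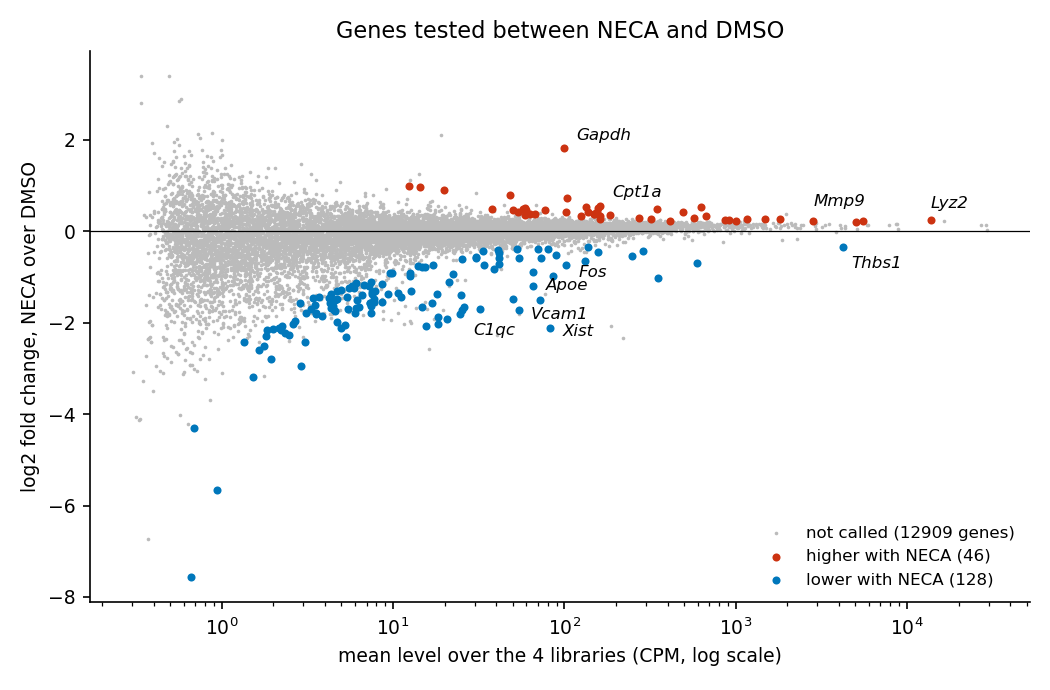
Log2 fold change of NECA over DMSO for each gene tested, against its mean level over the 4 libraries in CPM on a log scale. The 46 higher genes have a median of 0.38, with Gapdh the highest at 1.82, and the 128 lower genes a median of -1.48.

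The counts of changed genes depended on single libraries. They were 8 higher and 45 lower without DMSO replicate 1, 34 and 60 without DMSO replicate 2, 227 and 594 without NECA replicate 1, and 114 and 198 without NECA replicate 2. When a library is left out, the spread of its group is not seen. A gene whose NECA libraries disagreed can therefore pass without either of them, which does not show a stable change. With library size alone as the scale, an alternative chosen after seeing the data, 21 genes were higher and 217 lower. It shifted the median gene by -0.07 on the log2 scale, and 8.8% of its calls were higher against 26.4% with TMM.

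Among the higher genes with a mean of at least 20 CPM and a full symbol, the largest log2 fold changes after Gapdh (1.82, SE 0.08, adjusted p = 5.15e-07; Ensembl gene ENSMUSG00000057666, chromosome 6, 125161715 to 125166467, GRCm38) belonged to Acot1, Rab3gap2 and Cpt1a. Acot1, a cytosolic acyl-CoA thioesterase, rose by 0.79 (SE 0.10, adjusted p = 0.00292), Rab3gap2 by 0.72 (SE 0.07, adjusted p = 0.000344) and Cpt1a (chromosome 19, 3322334 to 3385733) by 0.56 (SE 0.08, adjusted p = 0.00409). Slc25a20, the carrier that works with Cpt1a in fatty acid import, rose by 0.46, and Scd2, a fatty acid desaturase, by 0.49. The cytokine receptor kinase Jak3 and the activin-like receptor kinase Acvrl1 both rose by 0.51, and S100a6, a calcium-binding protein, by 0.48. Asprv1, a protease, and Cyp4f18, which inactivates leukotriene B4, both rose by 0.53, and the interferon-related gene Ifit1bl2 rose by 0.49. Counts of several of these genes were uncertain: Gapdh had 90 annotated near-identical copies, Acot1 shared 826 bases with Acot2, Rab3gap2 overlapped Iars2, and Slc25a20 shared a stretch of 366 bases with other transcripts. Without DMSO replicate 1, Cyp4f18, Jak3, Acvrl1, Ifit1bl2, Scd2, S100a6, Slc25a20 and Cpt1a no longer passed (adjusted p = 0.0501 for Cyp4f18 to 0.198 for Slc25a20), and the value for S100a6 was 0.32. Ifit1bl2 also missed the threshold without DMSO replicate 2 (adjusted p = 0.0627) and without NECA replicate 1 (adjusted p = 0.0624).

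**Figure D2:**
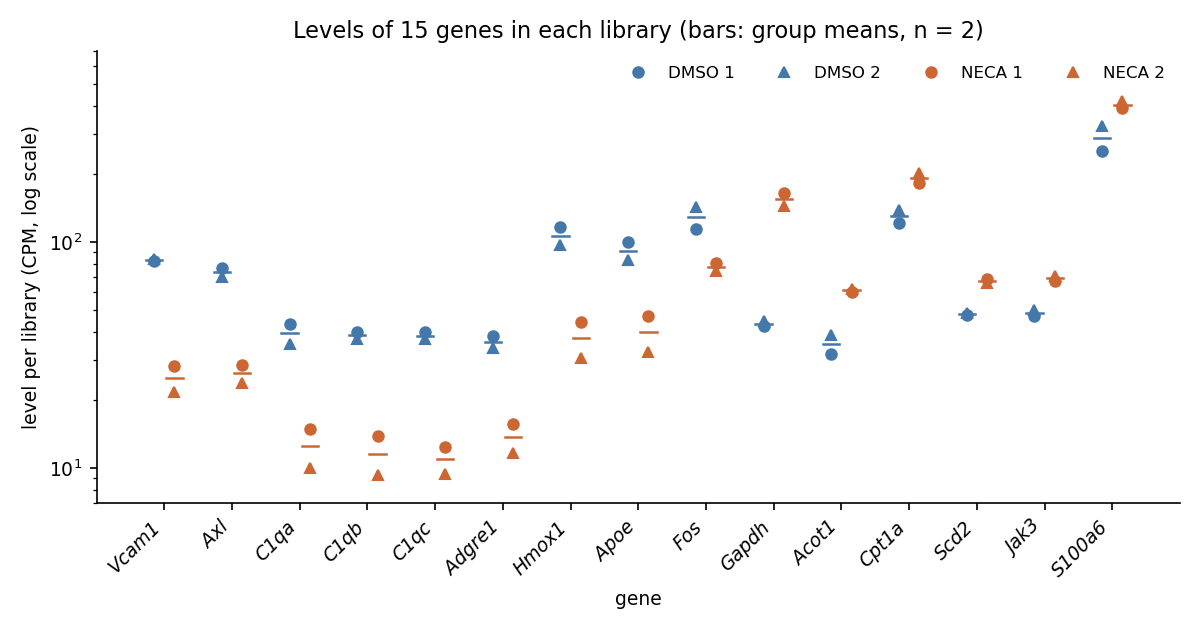
Levels of 15 genes in each library in CPM on a log scale, with circles for replicate 1, triangles for replicate 2 and a short line for each group mean (n = 2). In each gene both NECA libraries lie on the same side of both DMSO libraries, at 164 and 144 CPM against 42.5 and 44.7 CPM for Gapdh and at 28.3 and 21.7 CPM against 82.0 and 84.1 CPM for Vcam1.

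Among the lower genes with a mean of at least 20 CPM, those with the largest changes were mostly macrophage genes. Log2 fold changes were -1.92 (SE 0.19) for Fcna, a ficolin of complement activation, -1.81 (SE 0.14) for C1qc, -1.73 (SE 0.16) for C1qb, -1.65 (SE 0.17) for C1qa, -1.73 (SE 0.11) for Vcam1 and -1.50 (SE 0.14) for Hmox1, with adjusted p between 1.58e-05 and 0.000593. The 3 C1q genes lie next to each other on chromosome 4, from 136880129 to 136898803. Sdc3, a syndecan with counts uncertain beside an overlapping gene, fell by 1.71, Axl, a receptor for dying cells, by 1.49, the macrophage marker Adgre1 by 1.40, the lipoprotein gene Apoe by 1.19 and the plexin Plxnb2 by 1.12 on the log2 scale. Plxnb2 missed the threshold without DMSO replicate 1 (adjusted p = 0.117). Xist, the RNA of the inactive X chromosome, had the lowest value of them (-2.11, SE 0.39, adjusted p = 0.0217), at 204 and 64.1 CPM with DMSO and 25.6 and 36.9 CPM with NECA, and -1.04 without DMSO replicate 1. Of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, none was called, 0 of the 4 values lay below 0 (median 0.61), and all had their lowest level in DMSO replicate 1, where Xist was highest. The sex of the pups behind each library is not given in the labels, and no test adjusted for it. Its counts are uncertain because it overlaps the antisense gene Tsix.

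Markers of monocytes and macrophages fell as a list (camera, adjusted p = 1.28e-49; adjusted p = 0.43 with an estimated correlation), with a median log2 fold change of -1.21 over 28 tested members. Of these, 0 rose, 14 fell and 14 did not pass, and 0 rose and 19 fell adjusted over the list alone. Besides the C1q genes, Vcam1 and Hmox1, these included the transcription factors Maf (-1.79) and Spic (-1.57), the second of which directs red pulp macrophages. The most abundant of the 14 was the protease Ctsb, at 308 and 278 CPM with DMSO and 220 and 181 CPM with NECA. The abundant members Ly6c2 (0.11), Ctsd (-0.01) and Cd63 (0.04), which neutrophils and monocytes also express, were among those that did not pass. Counts of Maf, Ctsb, Ctsd, Ly6c2 and Cd22 are uncertain beside a near-identical annotated transcript. Ctsb missed the threshold without DMSO replicate 1 (adjusted p = 0.0956). Without NECA replicate 1 the value of Blnk was -4.29, and its call was lost without DMSO replicate 1 (adjusted p = 0.114) or DMSO replicate 2 (adjusted p = 0.217). Markers of B cells fell as a list (median -1.69, 18 tested, adjusted p = 4.69e-18; adjusted p = 0.43 with an estimated correlation). Only the adaptor Blnk (-2.43) passed over all genes, and 0 rose and 15 fell adjusted over the list alone. Cd22, a B cell lectin, stood at -1.74 (adjusted p = 0.056), Spib at -2.04 (adjusted p = 0.066) and Ms4a1 at -1.97 (adjusted p = 0.0879). Values of these 3 were -3.06, -4.17 and -4.37 without NECA replicate 1 and -1.10, -1.26 and -1.16 without NECA replicate 2. The NECA replicates differed, at 9.06 and 0.969 CPM for Ms4a1.

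Erythroid markers fell as a list (median -1.69, 20 tested, adjusted p = 1.94e-13; adjusted p = 0.43 with an estimated correlation). None of them passed edgeR's test over all genes (Hba-a2, whose counts are uncertain beside Hba-a1, had 42.2 and 13.9 CPM with DMSO and 8.68 and 0.323 CPM with NECA), and 0 rose and 16 fell adjusted over the list alone. T and NK cell markers fell as a list (median -1.46, 12 tested, adjusted p = 7.98e-06; adjusted p = 0.43 with an estimated correlation), with 0 members called by edgeR over all genes, and 0 higher and 6 lower adjusted over the list alone. Tcf7, a T cell transcription factor, stood at -1.51 (adjusted p = 0.0736) and the kinase Lck at -1.51 (adjusted p = 0.132). Hba-a2 (-2.58 with all libraries) stood at -6.41 and -1.69 without NECA replicates 1 and 2, and at -1.59 and -3.17 without DMSO replicates 1 and 2. Tcf7 stood at -1.92 without NECA replicate 1 and -1.21 without NECA replicate 2. Dendritic cell markers fell as a list (median -0.74, 12 tested, adjusted p = 0.000433; adjusted p = 0.43 with an estimated correlation), with Btla (-2.06) lower and 1 higher and 4 lower adjusted over the list alone. Markers of basophils, mast cells and eosinophils fell likewise (median -0.62, 18 tested, adjusted p = 3.24e-05; adjusted p = 0.43 with an estimated correlation), with the eotaxin receptor Ccr3 (-1.81) lower and 1 higher and 8 lower adjusted over the list alone. The medians of 4 of these lists depended on single NECA libraries: without NECA replicate 1 and without NECA replicate 2 they were -4.07 and -0.97 for B cells, -3.08 and -1.03 for erythroid cells, -1.42 and -0.37 for basophils, mast cells and eosinophils, and -1.10 and -0.29 for dendritic cells. The value of Btla was -3.56 without NECA replicate 1. Btla and Ccr3 did not pass without DMSO replicate 1 (adjusted p = 0.182 and 0.0925) or DMSO replicate 2 (adjusted p = 0.131 and 0.0655).

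**Figure D3:**
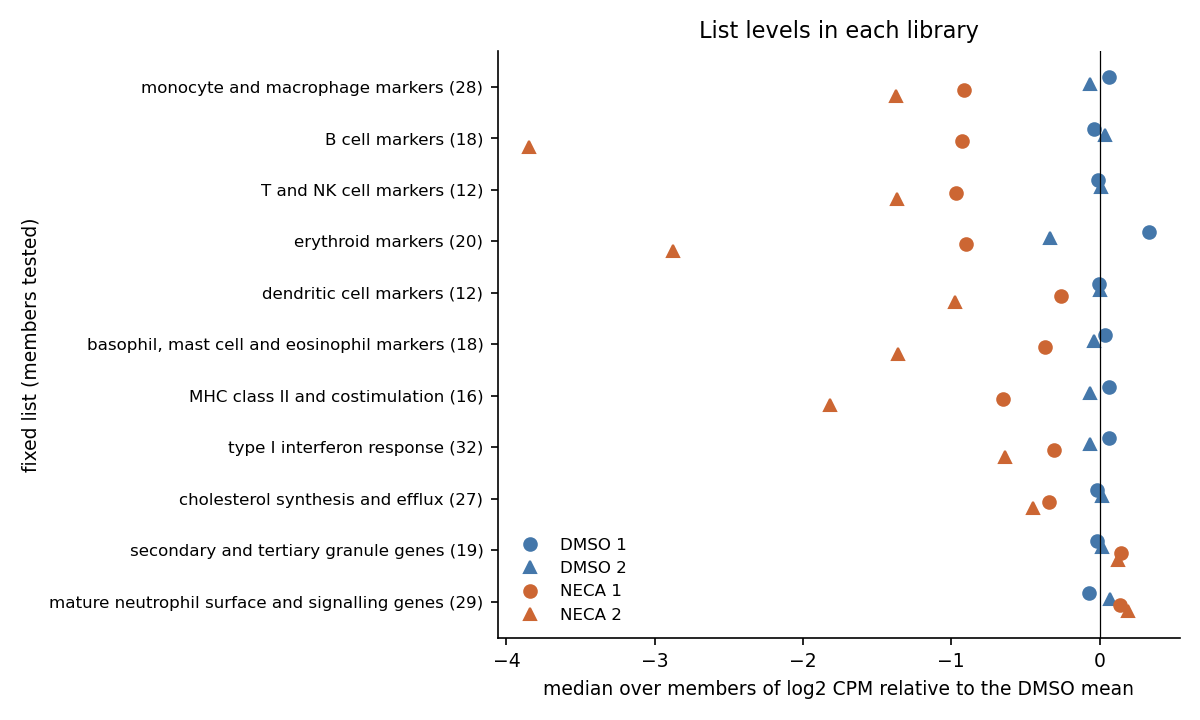
Median over the tested members of each list of log2 CPM relative to the DMSO mean, in each of the 4 libraries, with circles for replicate 1 and triangles for replicate 2. B cell markers lie at -0.93 in NECA replicate 1 and -3.85 in NECA replicate 2, macrophage markers at -0.91 and -1.38, and mature neutrophil genes at 0.14 and 0.19.

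Progenitor markers (median -0.14, 10 tested, adjusted p = 0.214) and megakaryocyte and platelet markers (median -0.07, 9 tested, adjusted p = 0.208) were not called as lists. Without NECA replicate 1 the progenitor list was called (median -0.36, adjusted p = 0.0389), while its median was -0.0050 without DMSO replicate 2 and -0.03 without NECA replicate 2. The platelet median ran from -0.02 without NECA replicate 1 to -0.19 without NECA replicate 2. Irf8, a transcription factor of monocyte and dendritic cell development, fell by 1.34 on the log2 scale among the progenitor markers, where 1 gene was higher and 2 were lower adjusted over the list alone. Thbs1, a secreted thrombospondin, was the 1 lower member of the platelet list (0 higher) over all genes and adjusted over the list alone. Its call over all genes was lost without DMSO replicate 2, where its value was -0.30. With DMSO, Thbs1 had 4548 and 4904 CPM against 0.679 and 0.690 CPM for the list member Pf4, so its fall cannot be read as a fall of platelets. The value for Irf8 was -2.09 without NECA replicate 1 and -0.88 without NECA replicate 2, and it did not pass without DMSO replicate 1 (adjusted p = 0.18) or DMSO replicate 2 (adjusted p = 0.139). Of the stromal and endothelial markers only 4 were tested, too few for a list test: Pecam1 stood at -0.68 and Tagln, whose counts are uncertain beside an annotated copy, at -0.81, and 0 were called by edgeR over all genes or adjusted over the list alone. Pecam1 passed without NECA replicate 1 (-1.17, adjusted p = 1.6e-05) and stood at -0.32 without DMSO replicate 2 and -0.33 without NECA replicate 2.

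Genes of the secondary and tertiary granules rose as a list (median 0.15, 19 tested, adjusted p = 4.62e-07; adjusted p = 0.43 with an estimated correlation) while the macrophage markers stood at a median of -1.21. The matrix proteases Mmp9 (0.23, adjusted p = 0.0126), Mmp8 (0.23, adjusted p = 0.0254) and Mmp25 (0.28, adjusted p = 0.0148) and haptoglobin, Hp (0.27, adjusted p = 0.0142), rose, 0 members fell and 15 did not pass, and 11 rose and 1 fell adjusted over the list alone. Mmp9 was among the most abundant transcripts, at 5135 and 5097 CPM with DMSO and 6150 and 5852 CPM with NECA. Genes of the mature neutrophil surface and its signalling rose as a list (median 0.16, 29 tested, adjusted p = 1.11e-09; adjusted p = 0.43 with an estimated correlation), with 28 of 29 log2 fold changes above 0. Over all genes, Lrg1, a secreted granule glycoprotein (0.42), rose and Cd14, a lipopolysaccharide co-receptor also made by macrophages (-0.78), fell, and 16 rose and 1 fell adjusted over the list alone. The chemotactic receptors Fpr1 (0.28, adjusted p = 0.068) and Ccr1 (0.31, adjusted p = 0.072) did not pass. Nor did S100a8 (0.23, adjusted p = 0.0755), S100a9 (0.13, adjusted p = 0.25) or the neutrophil surface marker Ly6g (0.13, adjusted p = 0.26). Without NECA replicate 1, Fpr1, Ccr1, S100a8 and S100a9 passed (adjusted p = 8.19e-15 to 0.00174), and Ccr1 and S100a8 also passed without DMSO replicate 2 (adjusted p = 0.0299 and 0.038) and NECA replicate 2 (adjusted p = 0.0138 and 0.00604). Values without DMSO replicate 1 were 0.20 for Ccr1, 0.15 for S100a8 and 0.04 for S100a9, which stood at 0.23 without DMSO replicate 2. Primary granule genes were not called as a list (median -0.15, 14 tested, adjusted p = 0.2): lysozyme, Lyz2, rose (0.24), Ctsc, the protease that activates granule proteases, fell (-0.95). Over the 14 members, 1 rose and 2 fell adjusted over the list alone. Mpo, a peroxidase with an overlapping annotated gene, stood at -1.19 (adjusted p = 0.121; counts uncertain) and Ms4a3 at -0.30. The primary granule list was called without DMSO replicate 1 (median -0.24, adjusted p = 0.0444). Mpo stood at -0.48 without DMSO replicate 2 and passed without any other library (adjusted p = 1.55e-06 to 0.0463). Counts of Lyz2 are uncertain because of Lyz1. The median of the mature neutrophil list was 0.10 without DMSO replicate 1 and 0.23 without DMSO replicate 2. The calls of Mmp9, Mmp25, Mmp8, Hp, Cd14 and Ctsc were lost without DMSO replicate 1 (adjusted p = 0.0582 to 0.157), and without DMSO replicate 2 those of Mmp9, Mmp25, Lyz2 and Cd14 were lost (adjusted p = 0.052 to 0.218).

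Of the adenosine receptor genes, Adora3 had 8.41 and 8.66 CPM with DMSO and 7.03 and 8.01 CPM with NECA (adjusted p = 0.727), with counts uncertain because it shares its locus with Tmigd3. Adora2a had 0.888 and 0.903 against 0.824 and 0.646 CPM (adjusted p = 0.883) and Adora2b 0.732 and 0.584 against 0.165 and 0.065 CPM (adjusted p = 0.192). Adora1, with 11, 5, 9 and 5 counts in the 4 libraries, was too low to test. Nt5e, the ectoenzyme that makes adenosine, stood at 0.14 (adjusted p = 0.336) and Entpd1, which acts before it, at -0.06 (adjusted p = 0.719). The list of adenosine receptors and purine handling was not called (median -0.07, 20 tested, adjusted p = 0.719), and 0 members were called by edgeR over all genes or adjusted over the list alone. Its smallest p-values belonged to Entpd3 (0.85, adjusted p = 0.0962), P2rx7 (-1.32, adjusted p = 0.121), Adora2b and Slc29a1, a nucleoside transporter (-0.64, adjusted p = 0.216). The list median was -0.03 without DMSO replicate 1 and -0.0030 without NECA replicate 2. Without NECA replicate 1, P2rx7 passed (adjusted p = 0.0365), and Adora3 and Adora2a stood at -0.09 and -0.47, against -0.28 and -0.12 without NECA replicate 2.

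Genes for the suppressive function of MDSC were not called as a list (24 tested, adjusted p = 0.719), whose median (0.05) and mean (-0.07) differed in sign. Hmox1 (-1.50) and Irf8 (-1.34), both also on lists of other cell types, fell, and 5 rose and 3 fell adjusted over the list alone. Galectin 3, Lgals3, stood at 0.19 (adjusted p = 0.089). Arg1, the arginase of suppressor cells, had 3, 4, 3 and 2 counts, Nos2 2, 0, 1 and 2, and Il10 1, 0, 0 and 0 counts in DMSO replicates 1 and 2 and NECA replicates 1 and 2, which was too few to test. Ptgs2, a prostaglandin synthase (-0.63, adjusted p = 0.591), the checkpoint ligand Cd274 (-0.79, adjusted p = 0.308; counts uncertain beside an overlapping gene) and Tgfb1 (-0.02, adjusted p = 0.95) did not pass. Lgals3 passed without NECA replicate 1 (adjusted p = 0.0487), and the list median was 0.10 without DMSO replicate 2. Ptgs2 stood at 0.09 without DMSO replicate 2 and -1.10 without DMSO replicate 1, and Cd274 at -0.27 without DMSO replicate 1. Tgfb1 stood at 0.05 and -0.08 without DMSO replicates 1 and 2, and at -0.17 and 0.11 without NECA replicates 1 and 2.

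Genes of the NADPH oxidase and oxidant handling were not called as a list (24 tested, adjusted p = 0.894), with a median of 0.02 and a mean of -0.13 and with 2 higher and 4 lower adjusted over the list alone. The oxidase subunits Cybb (0.05, adjusted p = 0.586) and Ncf1 (0.13, adjusted p = 0.125) and catalase, Cat (-0.40, adjusted p = 0.102), did not pass. The list median ran from -0.01 without DMSO replicate 1 to 0.07 without DMSO replicate 2, and Cybb stood at 0.03 without NECA replicate 1. Prdx1, a peroxiredoxin whose counts are uncertain beside its pseudogenes, fell (-0.75), but not without DMSO replicate 1 (adjusted p = 0.198) or DMSO replicate 2 (adjusted p = 0.0577).

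Inflammatory cytokines and chemokines fell as a list (median -0.17, 13 tested, adjusted p = 0.0448; adjusted p = 0.43 with an estimated correlation), with 0 members called by edgeR over all genes and 0 higher and 2 lower adjusted over the list alone. Tnf stood at 0.20 (adjusted p = 0.318), Il1b at -0.17 (adjusted p = 0.508), Il18 at -1.24 (adjusted p = 0.0769) and Ccl3 at -1.05 (adjusted p = 0.185), and Il6, with 3, 4, 3 and 0 counts, was not tested. Ccl3 passed without NECA replicate 1 (-1.91, adjusted p = 0.000552) and stood at -0.55 without NECA replicate 2, and Il1b ran from -0.06 without DMSO replicate 2 to -0.26 without DMSO replicate 1. Macrophage markers stood beside these at a median of -1.21. The cytokine list missed the threshold without DMSO replicate 2 (median -0.06, adjusted p = 0.336), NECA replicate 1 (-0.34, adjusted p = 0.0672) or NECA replicate 2 (-0.20, adjusted p = 0.0709), and its median was -0.26 without DMSO replicate 1. Targets of NF-kB were not called as a list (25 tested, adjusted p = 0.719), with a median of -0.0047 and a mean of -0.06, against whose sign camera leaned upward. By edgeR 0 of them were called over all genes or adjusted over the list alone. Tnfaip2 (0.18), Icam1 (-0.78; counts uncertain beside an overlapping gene), Cflar (0.16; counts uncertain) and Nfkb2 (-0.24; counts uncertain) had its smallest p-values. The median of the NF-kB list was above 0 without any 1 library (0.0010 to 0.06), and Nfkb2 stood at -0.15 without DMSO replicate 2.

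Immediate-early and heat-shock genes fell as a list (median -0.24, 17 tested, adjusted p = 0.0003; adjusted p = 0.43 with an estimated correlation). The transcription factors Fos (-0.73, adjusted p = 0.00359), Egr1 (-2.08, adjusted p = 0.00978) and Fosb (-1.44, adjusted p = 0.0372) fell, 0 rose and 14 did not pass, and 0 rose and 3 fell adjusted over the list alone. Fos had 115 and 142 CPM with DMSO and 80.3 and 74.1 CPM with NECA. Genes of the cAMP and CREB response, which lies downstream of some adenosine receptors, fell as a list (median -0.26, 25 tested, adjusted p = 0.019; adjusted p = 0.43 with an estimated correlation). This call was lost over the 21 members on no other list (adjusted p = 0.106), and macrophage markers stood beside both lists at a median of -1.21. Thbs1 (-0.36, adjusted p = 0.01) and the phosphatase Dusp1 (-0.38, adjusted p = 0.0372) fell, 0 rose, and 0 rose and 5 fell adjusted over the list alone. Sik1, a kinase induced by cAMP, stood at -0.32 (adjusted p = 0.0725) and Odc1, uncertain because of its pseudogenes, at -0.70 (adjusted p = 0.0652). Both passed without NECA replicate 1 (adjusted p = 0.00956 and 0.0312), Odc1 also passed without NECA replicate 2 (adjusted p = 0.0429), and Sik1 stood at -0.22 without DMSO replicate 2. Without DMSO replicate 2 the medians were -0.05 for the immediate-early list and -0.14 for the cAMP list (adjusted p = 0.261), and Egr1 stood at -1.35. The immediate-early median was -0.37 without DMSO replicate 1, and the cAMP median was -0.07 without NECA replicate 2 (adjusted p = 0.146). Dusp1 and Fosb were lost without DMSO replicate 1 (adjusted p = 0.115 and 0.18) and without DMSO replicate 2 (adjusted p = 0.18 and 0.104), and Thbs1 without DMSO replicate 2 (adjusted p = 0.0696).

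Cholesterol synthesis and efflux genes fell as a list (median -0.45, 27 tested, adjusted p = 1.05e-10; adjusted p = 0.43 with an estimated correlation), beside macrophage markers at a median of -1.21. Over all genes 4 members fell and 1 rose. The sterol-responsive transcription factor Srebf2 (-0.46, adjusted p = 0.0148), the sterol carrier Stard4 (-0.92, adjusted p = 0.0312) and Apoe (-1.19) were among those that fell, while the cholesterol exporter Abcg1 rose (0.38, adjusted p = 0.0319). Over all genes 22 members did not pass, and 2 rose and 13 fell adjusted over the list alone. Apoe had 99.5 and 82.8 CPM with DMSO and 47.1 and 32.6 CPM with NECA. Srebf2, Stard4 and Abcg1 were lost without DMSO replicate 1 (adjusted p = 0.105, 0.157 and 0.104) and without DMSO replicate 2 (adjusted p = 0.0759, 0.12 and 0.138).

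Genes of lipid uptake, storage and fatty acid oxidation went both ways and were not called as a list (median -0.0044, mean -0.30, 25 tested, adjusted p = 0.894). Cpt1a (0.56) and Plin2, which coats lipid droplets (0.35, adjusted p = 0.0177; uncertain beside a pseudogene), rose, and lipoprotein lipase, Lpl, fell (-1.16, adjusted p = 0.037), with 4 higher and 4 lower adjusted over the list alone. Pparg, a transcription factor of lipid handling, stood at -1.59 (adjusted p = 0.0654) and Dgat2, which makes triglycerides, at 0.23 (adjusted p = 0.063). Without DMSO replicate 1, Cpt1a, Plin2 and Lpl did not pass (adjusted p = 0.0512, 0.131 and 0.197), and without DMSO replicate 2 Plin2 and Lpl did not (adjusted p = 0.066 and 0.0801). Pparg and Dgat2 passed without NECA replicate 1 (adjusted p = 0.00322 and 0.0305), and the list median ran from -0.04 without DMSO replicate 1 to 0.04 without DMSO replicate 2.

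Glycolysis and hypoxia genes rose as a list (median 0.06, mean -0.04, 34 tested, adjusted p = 0.00758; adjusted p = 0.529 with an estimated correlation), so that the mean went against the test and the median. Beside this list stood macrophage markers at a median of -1.21 and B cell markers at -1.69. Gapdh (1.82) rose, the cytokine Mif (-1.13, adjusted p = 0.0492), whose counts are uncertain beside its pseudogenes, fell, 32 did not pass, and 3 rose and 1 fell adjusted over the list alone. Pyruvate kinase, Pkm (0.16, adjusted p = 0.0855; uncertain because of a pseudogene), and hexokinase 3, Hk3 (0.16, adjusted p = 0.112), did not pass. The list missed the threshold without DMSO replicate 1 (median 0.04, adjusted p = 0.254) or NECA replicate 1 (0.02, adjusted p = 0.126), and its median was 0.09 without DMSO replicate 2. Mif was lost without either DMSO library (adjusted p = 0.0905 without replicate 1 and 0.251 without replicate 2). Subunits of oxidative phosphorylation were not called as a list (median -0.01, 34 tested, adjusted p = 0.894), camera leaned upward against the sign of the median, and 0 members were called by edgeR over all genes or adjusted over the list alone. Its smallest p-values belonged to Ndufs3 (-0.31; uncertain beside a pseudogene), Cox6c (0.15), Uqcrb (-0.23; uncertain beside pseudogenes) and Cox5a (-0.16). Its median was 0.03 without DMSO replicate 2, where Cox5a stood at -0.0040. Pkm passed without NECA replicate 1 (adjusted p = 0.0223), and Uqcrb stood at -0.39 without NECA replicate 1 and -0.09 without NECA replicate 2.

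MHC class II and costimulation genes fell as a list (median -1.11, 16 tested, adjusted p = 8.52e-10; adjusted p = 0.43 with an estimated correlation), beside B cell markers at a median of -1.69. Only H2-DMa, which loads peptide onto class II molecules, was called over all genes (-1.32, adjusted p = 0.0326), and 0 rose and 11 fell adjusted over the list alone. Ctss stood at -1.07 (adjusted p = 0.056), H2-Ob at -1.77 (adjusted p = 0.102) and Cd83 at -1.42 (adjusted p = 0.111). Without NECA replicate 1 Ctss stood at -1.73 and H2-Ob at -3.73, and without NECA replicate 2 they stood at -0.65 and -1.01. Type I interferon response genes fell as a list (median -0.49, 32 tested, adjusted p = 1.11e-09; adjusted p = 0.43 with an estimated correlation), with 31 of 32 log2 fold changes below 0. Beside it stood macrophage markers at a median of -1.21, B cell markers at -1.69 and dendritic cell markers at -0.74. Irf7, the factor that amplifies the response, fell (-0.38, adjusted p = 0.038), and 0 rose and 7 fell adjusted over the list alone. Ifi204, uncertain because of related genes, stood at -0.39 (adjusted p = 0.0709) and Bst2, abundant in plasmacytoid dendritic cells, at -1.09 (adjusted p = 0.0768). Ifi204 passed without NECA replicate 1 (adjusted p = 0.0128). Alternative activation genes fell as a list (median -0.48, 15 tested, adjusted p = 5.21e-06; adjusted p = 0.43 with an estimated correlation), with 13 of 15 log2 fold changes below 0. The macrophage receptors Mrc1 (-1.88, adjusted p = 0.000446), Mertk (-1.37, adjusted p = 0.0113) and Cd163 (-1.67, adjusted p = 0.0188) were lower over all genes, with 1 higher and 5 lower adjusted over the list alone. Macrophage markers (median -1.21) share some of its members. Without NECA replicate 1 and without NECA replicate 2 the medians were -2.06 and -0.66 for the class II list, -0.66 and -0.31 for the interferon list and -1.13 and -0.18 for the alternative activation list, the last of which was -0.22 without DMSO replicate 1. Without DMSO replicate 1, H2-DMa, Irf7, Mertk and Cd163 did not pass (adjusted p = 0.1 to 0.182), without DMSO replicate 2 H2-DMa and Irf7 did not (adjusted p = 0.0818 and 0.139), and without NECA replicate 2 Irf7 did not (adjusted p = 0.0756).

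**Figure D4:**
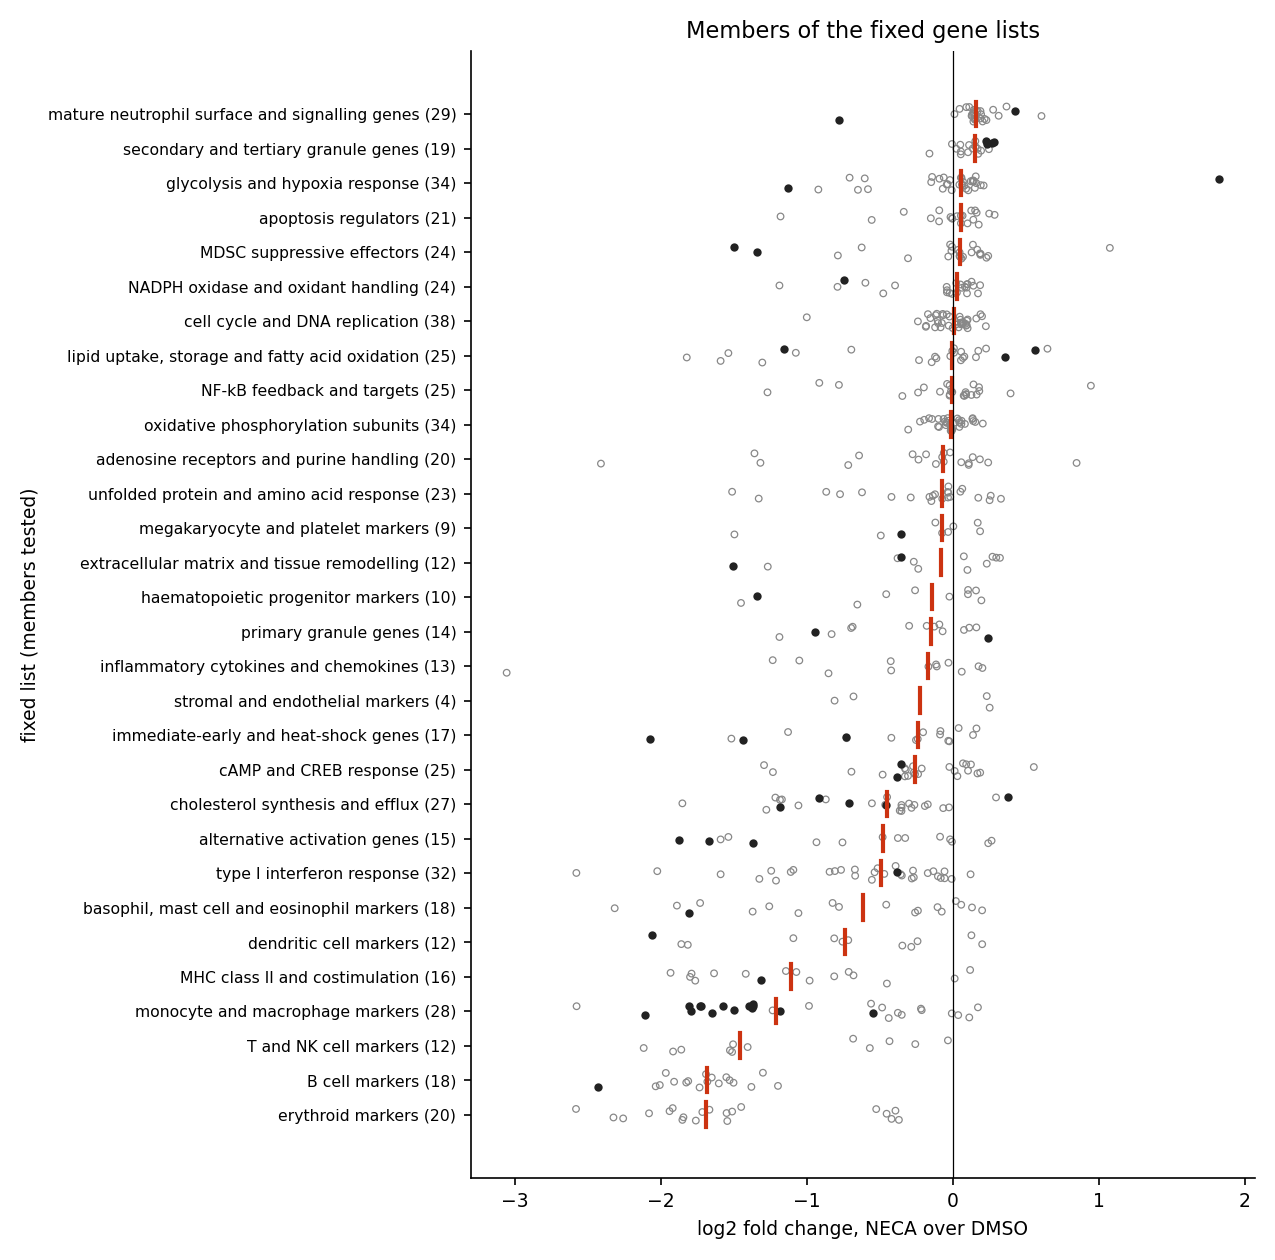
Log2 fold change of NECA over DMSO for each tested member of the 30 fixed lists, with filled points for members called over all genes, open points for the others and a vertical bar at the median. Medians run from 0.16 for mature neutrophil genes to -1.69 for B cell and erythroid markers.

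Cell cycle genes were not called as a list (median 0.01, mean -0.03, 38 tested, adjusted p = 0.719), nor were apoptosis regulators (median 0.05, mean -0.04, 21 tested, adjusted p = 0.344), and in both lists 0 members were called by edgeR over all genes or adjusted over the list alone. The mitotic cyclins Ccnb2 (0.23, adjusted p = 0.185) and Ccnb1 (0.20, adjusted p = 0.352; uncertain beside pseudogenes) and the apoptosis gene Bad (0.29, adjusted p = 0.251) did not pass. Without NECA replicate 1 the cell cycle list was called (median 0.13, adjusted p = 0.0392), as were Ccnb2 and Ccnb1 (adjusted p = 0.0422 and 0.0278), while its median was -0.04 without DMSO replicate 1 and -0.05 without NECA replicate 2. The apoptosis median was 0.02 without NECA replicate 1. Genes of the unfolded protein and amino acid response were not called as a list (median -0.07, 23 tested, adjusted p = 0.2), with 0 members called by edgeR over all genes and 1 higher and 1 lower adjusted over the list alone. Xbp1 stood at 0.25 (adjusted p = 0.0945) and Pdia4 at -0.62 (adjusted p = 0.102), and the list median ran from -0.03 without NECA replicate 2 to -0.15 without DMSO replicate 1. Extracellular matrix and tissue remodelling genes were not called as a list (median -0.08, 12 tested, adjusted p = 0.753), but Thbs1 (-0.36) and the growth factor Igf1 (-1.51, adjusted p = 0.0201), which red pulp macrophages make, fell, with 2 higher and 2 lower adjusted over the list alone. Thbs1 was among the most abundant of the lower genes, at 4548 and 4904 CPM with DMSO and 3918 and 3472 CPM with NECA. The matrix list median was 0.10 without DMSO replicate 2, 0.02 without NECA replicate 1 and 0.03 without NECA replicate 2, but -0.07 without DMSO replicate 1. Igf1 did not pass without DMSO replicate 1 (adjusted p = 0.115) or DMSO replicate 2 (adjusted p = 0.0851), nor Thbs1 without DMSO replicate 2 (adjusted p = 0.0696).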

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

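Library size alone, thinning and removal of the genes of other cell types were chosen after seeing the data. In no refit did any of the 174 called genes that were tested change sign. With DESeq2 size factors, upper-quartile scaling, the stricter filter, thinned libraries or without the genes of other cell types, both counts stayed within 1.5 times of 46 higher and 128 lower. Other counts of higher and lower genes were 285 and 590 with no filter on low counts, 122 and 198 with limma-voom, 21 and 217 with library size alone, 8 and 34 at adjusted p under 0.01, 1 higher with a 2-fold minimum, and 143 higher with the DESeq2 test. With unadjusted p and a 2-fold minimum 591 were lower. Leaving out 1 library gave 8 to 227 higher and 45 to 594 lower genes, fewest without DMSO replicate 1 and most without NECA replicate 1. In 3 limma tests on FPKM, 0 genes were higher and 0 lower, while 1302 (pseudocount 1), 1267 (pseudocount 0.1) and 1018 (quantile-normalized) had an unadjusted p under 0.05. The cause of these differences was not tested. With a replicate block, counts were 123 higher and 298 lower, and all 174 calls were kept. The labels do not say what a replicate number shares, so the numbers were not taken to pair the samples. The deviations of same-numbered libraries correlated at r = 0.022 over all genes, which cannot exclude a shared preparation. Xist had 204 CPM in DMSO replicate 1 and 25.6 CPM in NECA replicate 1, and the Y-linked genes named above were lower in DMSO replicate 1. Unless NECA itself changed these genes, this argues against a single pool of pups split between these libraries. It does not speak to a shared day or batch, nor to the libraries numbered 2 (Xist at 64.1 and 36.9 CPM). Of the lists, 3 were higher and 13 lower; with an estimated correlation and with fry 0 were higher and 0 lower, although camera's estimated correlation gave an unadjusted p of 0.0364 for the macrophage list. With quantile-normalized FPKM 1 list was higher, and oxidative phosphorylation, which camera placed above the other genes in the counts, fell below them (median -0.045, adjusted p = 0.0299). Leaving out 1 library gave 2 to 3 higher and 11 to 14 lower lists. Of 87 named genes that were not called, 1 passed without DMSO replicate 1, 3 without DMSO replicate 2, 35 without NECA replicate 1 and 14 without NECA replicate 2, and the values of 40 moved by over 1.5 times in at least 1 of these. The median level of the lower genes was 7.56 CPM, and Arg1, Nos2, Il10, Il6 and Adora1 were too low to test.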

Other observations

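The tests of 1 dilution factor, of the C1q fold, of the genes with many copies, of the glycolysis list, of unequal granule genes and of the level of the Gapdh copies were chosen after their results were seen, as were the genes named in the next paragraphs. Of the 174 called genes, 128 were on no fixed list, 36 of them higher and 92 lower. Several lower ones are known from splenic red pulp and marginal zone macrophages: the integrin Itgad (-1.57, adjusted p = 0.000344), the scavenger receptor Stab2 (-1.80, adjusted p = 0.00359), the sialic acid receptor Siglec1 (-1.49, adjusted p = 0.0148) and the secreted protein Cd5l (-1.58, adjusted p = 0.00836). Gimap3 (-2.32, adjusted p = 0.00313) and the B cell factor Bach2 (-2.59, adjusted p = 0.0417) were lower too. Single genes that fell included nucleolin, Ncl (-0.39, adjusted p = 0.0201), nucleophosmin, Npm1 (-0.57, adjusted p = 0.0492), and Myc (-2.23, adjusted p = 0.0409). Of 91 protein-coding genes whose symbols begin with Rpl or Rps and a digit, 1 fell and 0 rose, with 75 values below 0 (median -0.15). Most such symbols belong to cytosolic ribosomal proteins, but some other genes share this form. Single genes that rose included Actb (0.20, adjusted p = 0.0199), Actn1 (0.24, adjusted p = 0.0352) and Selplg, the selectin ligand of neutrophils (0.28, adjusted p = 0.0427). No list of such genes was tested. The transcriptional repressor Bcl6 (0.43, adjusted p = 0.00586) and Csf2ra, a subunit of the GM-CSF receptor (0.24, adjusted p = 0.0273), rose as well. Counts of Itgad, Bach2, Npm1 and Actn1 are uncertain beside near-identical annotated transcripts. Without DMSO replicate 1, Siglec1, Cd5l, Bach2, Ncl, Npm1, Actb, Actn1, Selplg, Bcl6 and Csf2ra were not called (adjusted p = 0.0582 to 0.198). Without DMSO replicate 2, Bach2, Ncl, Npm1, Myc, Actb, Actn1, Selplg and Csf2ra were not (adjusted p = 0.0627 to 0.254), nor was Npm1 without NECA replicate 2 (adjusted p = 0.144).

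All 11 tested protein-coding genes of the mitochondrial genome had log2 fold changes below 0 (median -0.41), and 4 fell. The smallest p-values belonged to mt-Nd1 (-0.65, adjusted p = 0.00303) and mt-Cytb (-0.43, adjusted p = 0.00661), both subunits of the respiratory chain. The other 2 were mt-Nd2 (-0.58) and mt-Nd6 (-0.41). Without DMSO replicate 1, mt-Nd2 and mt-Nd6 did not pass (adjusted p = 0.0533 and 0.114), without DMSO replicate 2 neither these nor mt-Cytb did (adjusted p = 0.0643, 0.197 and 0.0578), and without NECA replicate 2 mt-Nd6 did not (adjusted p = 0.0899), so that 2, 1 and 3 of the 4 were left. The 2 mitochondrial ribosomal RNAs, mt-Rnr1 (0.09) and mt-Rnr2 (0.12), did not pass. The Y-linked genes Ddx3y and Eif2s3y had their lowest levels in DMSO replicate 1, at 13.5 and 34.2 CPM, where Xist was highest at 204 CPM; in DMSO replicate 2 and NECA replicates 1 and 2 they had 30.0, 37.8 and 40.3 CPM and 75.1, 84.0 and 78.3 CPM. The Xist value of -2.11 (-1.04 without DMSO replicate 1) may reflect a different mix of male and female pups and not NECA, which was not tested.

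The lists of macrophage, B cell, T and NK cell and erythroid markers fell by camera (each with adjusted p = 0.43 with an estimated correlation), although over all genes 14, 1, 0 and 0 of their members were called. A single dilution of all other cell types would keep erythroid and macrophage markers in 1 ratio. Between NECA replicates 2 and 1 their median log2 ratios differed by -1.90 (erythroid minus macrophage, 95% bootstrap interval over genes -2.66 to -0.99). Between the DMSO replicates they differed by -0.53 (-1.16 to -0.13), so this ratio also varied without NECA. Each contrast set 1 library against 1 other, and the genes are not independent. These values argue at most against 1 common factor. Carry-over that differs by library and by cell type would also shift this ratio, so it stayed open for all of these lists. With libraries thinned to 1 size 14 macrophage genes were still lower, which argues against depth. Fewer macrophages carried over with unchanged transcripts stayed open: 0 of 25 other tested members lay more than 2 SE below the C1q mean of -1.73, but C1q was picked from the most lowered members, so this count decides nothing. Of the 28 tested members 24 are on no other list, and Ctsb at 293 CPM with DMSO was among the most abundant. A candidate biological explanation, that NECA lowered the survival of macrophages and other cells during the 5 days or their transcripts, was not tested.

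Gapdh rose 3.54-fold, more than any other gene of at least 20 CPM that passed. For reads shared with its annotated copies, the log2 fold change of Gapdh and copies summed was 1.10 (2 SE interval 0.97 to 1.23), which missed the bound of above 1 that had been set in advance against this cause, but by a comparison added after that result the copies held 57.6 and 52.8 CPM with DMSO and 55.2 and 59.6 CPM with NECA while Gapdh gained 111 CPM, which argues against it. The other 179 tested genes with at least 10 such copies had a median of -0.05 and a 90th percentile of 0.44, and the other 33 glycolysis genes a median of 0.05 and a 90th percentile of 0.16, which argues against a shift of either class by the amount of Gapdh. Of the 179 genes 3 were called higher and 0 lower, against 46 and 128 of all 13083 tested. Reads left out of the tables because they match several genes were not tested, and none of these comparisons can see them. A biological rise of Gapdh itself with NECA thus remained a hypothesis that was not tested.

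The list of secondary and tertiary granule genes rose by camera (median 0.15; adjusted p = 0.43 with an estimated correlation, 0.237 with fry), with 4 of 19 members called over all genes. A higher share of neutrophil RNA would raise alike only members that no other cell type expresses, and which members these are was not examined. The 19 tested members differed among themselves, from -0.16 to 0.28 (Cochran's Q of 123 on 18 degrees of freedom, across genes that are not independent). This spread therefore does not decide on a higher neutrophil share as the whole cause. Relative to all genes, the median of the list was 0.16 before and 0.16 after removal of the trend on GC content and transcript length, which between its 5th and 95th percentiles ran only from -0.03 to 0.06, and this argues against such a bias as the cause. A shift from fewer other cells, as part or all of the rise, stayed open, as did an effect of NECA on single granule genes, which was not tested.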
